A study of Homo sapiens with 6 samples.

How the data were processed

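RNA of HeyA8 cells was measured in 6 libraries: 2 with siScr, 2 with siCAG/CUG and 2 with siCGA/UCG, each 48 h after transfection with 1 nM of the siRNA. Per the labels, total RNA was isolated with a column kit and treated with DNase, libraries were made with an Illumina total RNA kit, and they were sequenced on a HiSeq4000. The labels list TopHat, Bowtie2 and HTSeq with the genome build hg38, without versions. The strand setting of the counting is not given, so reads of genes that overlap on opposite strands cannot be told apart. The authors deposited 2 tables, 1 per repeat siRNA, each with 26485 genes and the 4 libraries compared.

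The deposited expression values are CPM, which the authors made by dividing each library's gene counts by their sum, with no scaling factor; every column sums to the same total. The deposited log2 fold changes and average log2 CPM come from the authors' edgeR fit of the 4 libraries of each table, per the file headers. The deposited p-values come from the authors' edgeR likelihood ratio test, per the file headers, and the adjusted p-values from the Benjamini-Hochberg method over the 26485 genes. The tables also mark survival genes (1844) and nonsurvival genes (312) without saying how they were chosen. The siScr columns of both tables are identical in all 26485 genes. The CPM values are multiples of 1 read, within a tolerance of 0.001 reads in 100% of the values, so whole reads could be recovered. The libraries held 51250822 and 50495205 (siScr), 49741755 and 53143919 (siCAG/CUG) and 46718268 and 50058238 (siCGA/UCG) reads assigned to genes. A spreadsheet had turned 28 gene names into dates, of which 27 were repaired. The tables hold no mitochondrially encoded genes, so the list of mitochondrially encoded mRNAs could not be tested.

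The analysis used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 for tables and figures. Genes with at least 0.2 CPM, about 10 reads, in at least 2 libraries were kept, which left 14243. The values log2(CPM + 0.5) of all 6 libraries were fitted in 1 limma model with a mean per group and an intensity trend. The pseudocount corresponds to 25.1 reads. The fit has 3 residual degrees of freedom, raised to 19.94 by the moderation across genes. Each repeat siRNA was compared with siScr, and both with each other. P-values of genes are moderated t-test p-values from limma, adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Values are group means with SD over 2 libraries, and log2 changes with their SE. The plan, written before the data were examined, named an edgeR quasi-likelihood test for raw counts and limma on log2 values for tables without counts. For the limma case it named the libraries in 2 ways, within each table and all 6 together where siScr is shared; all 6 were taken because the siScr columns are identical, and the fit of 4 libraries is among the alternatives. On simulated data, in which 14053 genes passed the filter, the fit recovered 57 of 67 genes changed by 0.5 on the log2 scale, 57 of 67 changed by 1 and 66 of 66 changed by 2, and called 22 unchanged genes, 0.159%. The simulated changes were few and went both ways, so this share does not carry over to a comparison in which most genes change.

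The 29 gene lists were fixed with the plan, and 27 had at least 3 tested members. They were tested with limma camera with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Counts of members called are given over all tested genes and adjusted over the list alone. The survival and nonsurvival marks were added as lists after the files were seen. Genes with repeats were found in GENCODE release 29: a gene carries a repeat if any annotated transcript holds an uninterrupted run of at least 19 nt in any phase. Of the tested genes, 13814 had a GENCODE transcript sequence. CAG and CTG carriers were tested with camera, adjusted over these sets, with Fisher's exact test, and by permutation, with 10000 draws of other genes matched on mean expression, transcript length and GC content. The overlap of calls was compared with the product of the counts over the genes tested and with 100 simulations of unchanged groups that share the siScr libraries.

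The named genes were chosen by rule. The rule takes the 10 largest rises and falls of protein-coding genes against siScr with an adjusted p under 0.05, a mean of at least 50 reads, and both treated libraries on the same side of both siScr libraries. It adds up to 4 called members per list with the smallest adjusted p, HTT, FAS, FASLG, CDKN1A, the repeat expansion disease genes, the 8 longest runs among called falls, and the 6 largest differences each way between both siRNAs.

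The alternatives were TMM factors, DESeq2 size factors, library sizes without the 20 most abundant genes, no filter, a mean of at least 1 CPM, pseudocounts of 0.1 and 1 CPM, a loess correction for GC content and transcript length, the replicate number as a block, only the 4 libraries compared, leaving out each library in turn, edgeR quasi-likelihood, limma-voom and DESeq2 on recovered reads, the authors' deposited results, and a change of at least 1.5-fold. For lists and repeats they were camera with an estimated correlation, edgeR camera on recovered reads, fry, runs of at least 18 or 21 nt, protein-coding transcripts only and matched genes. TMM factors, both pseudocounts, edgeR quasi-likelihood with recovered reads and edgeR camera were written into the alternatives after the files were seen to hold CPM.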

Results

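HeyA8 is an established human ovarian cancer cell line. Its total RNA was sequenced 48 h after treatment with 1 nM of 1 of 3 small interfering RNAs (siRNAs). The duplex siCAG/CUG pairs a strand of CAG repeats with a strand of CUG repeats, and the duplex siCGA/UCG pairs CGA repeats with UCG repeats. The nontargeting siScr served as the control of both. Each group held 2 libraries, 6 in all, and the values below are means with n = 2 per group. The libraries held 46718268 to 53143919 reads assigned to genes, so that 1 read equalled 0.0188 to 0.0214 CPM, the unit of the values below. A total of 14243 genes were tested. The first principal component carried 93.4% of the variance and parted the siCAG/CUG libraries from the other 4; the second carried 4.27% and parted siCGA/UCG from siScr. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. CPM give each gene's share of a library and do not show a change in the total RNA of a cell. Fitted log2 changes include a pseudocount, which pulls those of genes at low levels toward 0.

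The comparison of siCAG/CUG with siScr asked which genes a CAG and CUG repeat duplex, described in the series title as toxic to cancer cells, changed. The genes that fell furthest include many of cell division. The largest falls were in HJURP, a chaperone of the centromeric histone, from 208 ± 3.4 (SD) to 4.63 ± 0.61 CPM, and in DLGAP5, NUF2, CDK1, TTK, DEPDC1, ASPM, PBK, KIF20A and TOP2A, with log2 changes from -5.35 to -5.12. CDK1, the kinase that drives entry into mitosis, fell from 283 ± 0.78 to 7.17 ± 0.61 CPM. The largest rises were in ANGPTL4, a secreted regulator of lipoprotein lipase, from 2.88 ± 0.13 to 106 ± 4.3 CPM, and in CPA4, TMEM132B, SCG5, IL6, SULF2, CITED2, ICAM1, CCND2 and C1S, with log2 changes from 4.98 to 3.51. These 20 genes had both siCAG/CUG libraries on the same side of both siScr libraries, and their SE was at most 0.138 on the log2 scale. HJURP (ENSG00000123485) lies on chromosome 2 at 233836701 to 233854566 and ANGPTL4 (ENSG00000167772) on chromosome 19 at 8364127 to 8374375 (hg38). By limma, 11049 of the 14243 genes passed an adjusted p of 0.05, of which 5128 were higher and 5921 lower with siCAG/CUG. Which direction held more genes depended on the scaling: TMM factors in the same fit gave 5610 higher and 5488 lower, DESeq2 size factors 5595 and 5521, and library sizes without the 20 most abundant genes 5731 and 5387; the deposited table has 5771 and 5579. With a change of at least 1.5-fold as well, 5220 passed, 2269 higher and 2951 lower.

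Every tested member of the 3 proliferation lists fell with siCAG/CUG. All 52 genes of G2/M and mitosis fell, with a median log2 change of -4.58, among them CENPF (-4.59 ± 0.031, SE) and ANLN (-4.67 ± 0.034). All 54 genes of S phase and DNA replication fell, with a median of -3.18, among them RRM2, a subunit of ribonucleotide reductase (-4.86 ± 0.041), and MCM4 and MCM7 of the replicative helicase (-3.82 ± 0.03 and -3.66 ± 0.038). All 57 replication-dependent histone genes fell, with a median of -3.93, among them HIST1H3G (-5.06 ± 0.04) and HIST1H1D (-5.05 ± 0.04); histone copies are near identical in sequence, so the gene to which a read belongs is uncertain. The 3 lists had adjusted p = 8.5e-31, 1.2e-25 and 9.1e-29 by limma camera with a preset correlation of 0.01, and adjusted p = 0.02, 0.02 and 0.069 with an estimated correlation. For G2/M and S phase, the call held with the estimated correlation; none of the other 25 fixed lists kept its call that way in this comparison.

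Targets of p53 rose with siCAG/CUG: 34 of 39 rose and 4 fell, with a median log2 change of 0.85 (adjusted p = 1.4e-10, and adjusted p = 0.092 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 272 ± 12 to 1621 ± 20 CPM (log2 change 2.57 ± 0.033, SE). MDM2, which targets p53 for degradation, rose by 1.45 ± 0.03, and TP53INP1 by 3.04 ± 0.04, whereas SFN fell (-3.22 ± 0.057). Of 26 genes of NF-kB and inflammation, 22 rose and 3 fell, with a median of 1.08 (adjusted p = 6.7e-07; adjusted p = 0.20 with an estimated correlation). The cytokine IL6 rose from 1.1 ± 0.1 to 19.9 ± 1.4 CPM, the adhesion receptor ICAM1 from 8.83 ± 0.093 to 109 ± 0.11, and BIRC3, an inhibitor of apoptosis, from 19.6 ± 0.18 to 129 ± 0.18. Of 37 interferon-stimulated genes, 24 rose and 6 fell (median 0.44, adjusted p = 0.00059; adjusted p = 0.31 with an estimated correlation); STAT2 rose by 1.83 ± 0.048, and the RNA sensor gene OAS3 fell by 1.41 (SE 0.074). Of 31 extracellular matrix and mesenchymal genes, 20 rose and 9 fell (median 0.55, adjusted p = 0.0023; adjusted p = 0.33 with an estimated correlation), with fibronectin, FN1, at 2.34 ± 0.043 and COL6A1 at 3.19 ± 0.061. Of 25 genes of NRF2 and oxidative stress, 14 rose and 8 fell (median 0.34, adjusted p = 0.0096; adjusted p = 0.20 with an estimated correlation), with the ferritin chains FTL at 1.66 ± 0.034 and FTH1 at 2.27 ± 0.04.

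Of 25 cholesterol biosynthesis genes, 23 fell and 2 rose, with a median log2 change of -1.26 (adjusted p = 2.8e-08; adjusted p = 0.20 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, fell from 409 ± 8.1 to 62.5 ± 1.1 CPM. Of 40 core spliceosome genes, 36 fell and 2 rose (median -0.46, adjusted p = 3.4e-07; adjusted p = 0.069 with an estimated correlation), including SNRPD1 (-1.36 ± 0.038) and CDC5L (-1.27 ± 0.034). Of 20 cytosolic aminoacyl-tRNA synthetases, 16 fell and 2 rose (median -0.48, adjusted p = 0.0014; adjusted p = 0.35 with an estimated correlation), with GARS at -1.67 ± 0.039. Of 31 proteasome subunits, 25 fell and 3 rose (median -0.31, adjusted p = 0.00073; adjusted p = 0.33 with an estimated correlation), and of 72 mitochondrial ribosomal proteins, 43 fell and 11 rose (median -0.22, adjusted p = 0.017; adjusted p = 0.33 with an estimated correlation). Of 14 heat shock genes, 10 fell and 3 rose (median -0.51, adjusted p = 0.036; adjusted p = 0.33 with an estimated correlation), with the chaperone HSP90AA1 at -1.83 ± 0.049. Of 79 cytosolic ribosomal proteins, 67 rose and 5 fell (median 0.26, adjusted p = 4.7e-10; adjusted p = 0.33 with an estimated correlation). RPL14 stood apart from the other members and fell from 660 ± 20 to 23.4 ± 0.049 CPM, a log2 change of -4.79 ± 0.032. Of 18 genes of the RNA interference machinery, 12 fell and 3 rose (median -0.32, adjusted p = 0.036; adjusted p = 0.26 with an estimated correlation), with AGO1 at -1.12 ± 0.051. Of 9 epithelial markers, 7 fell and 1 rose (median -0.76, adjusted p = 0.039; adjusted p = 0.33 with an estimated correlation), with the keratin KRT18 at -1.37 ± 0.029. The calls of the RNA interference, mitochondrial ribosomal, proteasome and epithelial lists were lost in edgeR camera on recovered reads, with adjusted p = 0.20, 0.42, 0.11 and 0.091. Across the lists and all alternatives but leaving out a library, 24 of 260 values of this comparison lost a call. These include the losses with an estimated correlation, and not all are named here. The epithelial call was also lost without siScr library 2 (adjusted p = 0.06) and without siCAG/CUG library 2 (adjusted p = 0.058).

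**Figure D1:**
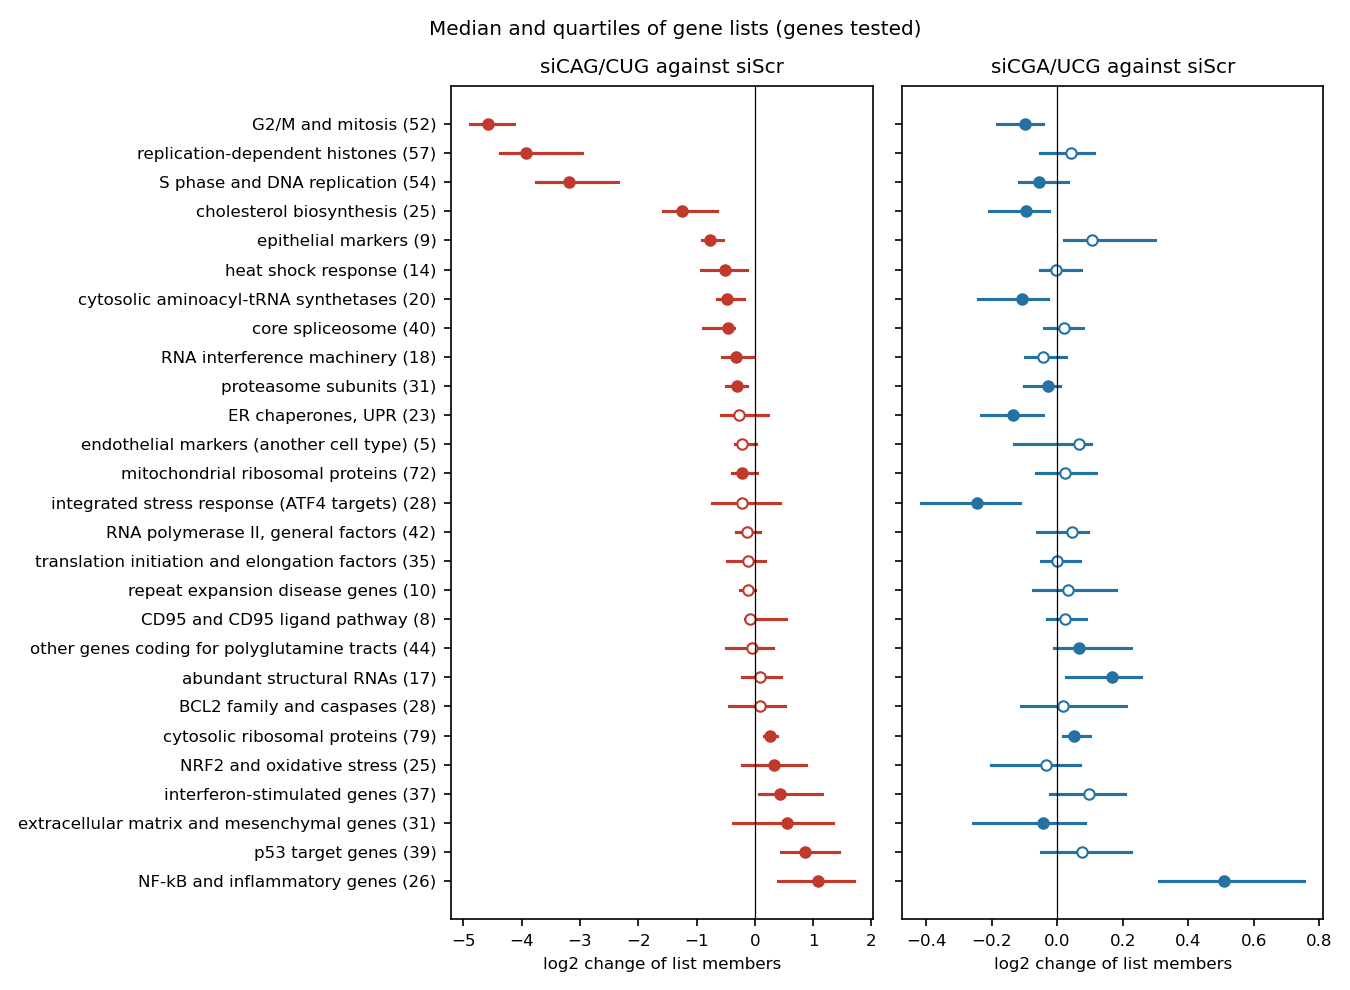
Median (point) and quartiles (line) of the log2 change of the tested members of each gene list, with siCAG/CUG (left) and siCGA/UCG (right) against siScr; the number of genes tested is in parentheses, filled points passed an adjusted p of 0.05 with the preset correlation, and the axes differ in scale. With siCAG/CUG the G2/M list lies at -4.58 and the NF-kB list at 1.08; with siCGA/UCG they lie at -0.10 and 0.51.

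Other lists did not pass the test with siCAG/CUG. Of 10 genes of repeat expansion diseases, 2 were higher and 3 lower (adjusted p = 0.88). HTT, whose CAG run codes for the glutamine tract expanded in Huntington's disease, stood at 50.5 ± 3.2 CPM in siScr and 50.6 ± 1.6 in siCAG/CUG (log2 change 0.00 ± 0.048, adjusted p = 0.98); after a correction for GC content and length its change was -0.19, which passed the threshold. ATXN1 was higher (1.42 ± 0.069) and TBP lower (-1.02 ± 0.073). The CD95 list had 3 of 8 members higher and 3 lower (adjusted p = 0.49), with the death receptor gene FAS at 0.91 ± 0.043; its ligand FASLG was not tested because its level was under the filter. The other lists were RNA polymerase II and general transcription factors (42 genes, 10 higher, 23 lower, adjusted p = 0.39), translation factors (35 genes, 12 higher, 19 lower, adjusted p = 0.38), ATF4 targets of the integrated stress response (28 genes, 10 higher, 14 lower, adjusted p = 0.74), endoplasmic reticulum chaperones (23 genes, 7 higher, 14 lower, adjusted p = 0.23) and the BCL2 family and caspases (28 genes, 13 higher, 10 lower, adjusted p = 0.29). Among the other genes with polyglutamine tracts, 18 of 44 were higher and 21 lower (adjusted p = 0.95); their median of -0.05 had the opposite sign of the test and turned to 0.01 with TMM factors. The CD95 list had a median of -0.07, which turned to 0.03 after the correction for GC content and length, and a mean of 0.15. Endothelial markers had 2 of 5 lower (adjusted p = 0.49), with CDH5, known as a cadherin of endothelial junctions, at 21.9 ± 1.8 CPM in siScr and 0.46 ± 0.15 in siCAG/CUG. Of the leukocyte markers, 2 were tested, too few for a list test, and CD68 was lower (-0.32 ± 0.061). Of 17 abundant structural RNAs, 8 were higher and 4 lower (adjusted p = 0.10), with MALAT1 at 1.82 ± 0.061. Adjusted over the list alone, the counts with siCAG/CUG were those given, except for repeat expansion disease genes (2 lower) and endothelial markers (1 lower). The authors marked survival and nonsurvival genes in their tables without saying how they chose them, so whether they were chosen on these samples is not known. Of 1770 tested survival genes, 434 rose and 1095 fell (437 and 1097 adjusted over the list alone), with a median of -0.28 (adjusted p = 1.5e-06; adjusted p = 0.00054 with an estimated correlation). Of 192 nonsurvival genes, 69 were higher and 72 lower (adjusted p = 0.62), with a median of 0.04 and a mean of -0.04. With siCGA/UCG, 369 survival genes were higher and 262 lower (374 and 266 adjusted over the list alone), and 34 nonsurvival genes were higher and 36 lower (34 and 37 adjusted over the list alone); both lists had adjusted p = 0.53.

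A second question was whether transcripts that carry repeats complementary to an siRNA strand changed. A CAG strand can pair with CUG repeats in RNA, which appear as CTG in the annotation. Genes with an uninterrupted CTG run of at least 19 nt fell with siCAG/CUG: 60 of 79 fell and 12 rose, with a median log2 change of -1.08 (adjusted p = 4.2e-08; adjusted p = 0.038 with an estimated correlation). The share that fell, 75.9%, compared with 41.4% of the other tested genes, an odds ratio of 4.47 (Fisher's exact test, two-sided, p = 6.0e-10). In a permutation test, none of 10000 draws of genes matched on expression, transcript length and GC content had as low a median, which gives p = 0.0002, the smallest possible with these draws. None of the 79 genes belonged to the 3 proliferation lists. The share that fell was 41.6% of genes with a CTG run under 12 nt and 47.4%, 62.5%, 71.1% and 78% of genes with runs of 12 to 14, 15 to 17, 18 to 20 and at least 21 nt. With siCGA/UCG the same 79 genes had a median of 0.00, 17 were higher and 15 lower (19 and 18 adjusted over the list alone; adjusted p = 0.73).

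RPL14 (ENSG00000188846) fell furthest among the 8 genes with the longest CTG runs among the falls. Its 32 nt run lies in the coding sequence of exon 6 of 6, on chromosome 3 at 40462030 to 40462061. LRP8, a receptor of the LDL receptor family, holds a 35 nt run in the coding sequence of exon 1 and fell from 105 ± 1.6 to 20.8 ± 1.7 CPM. BRI3BP, with a 29 nt run in the coding sequence of exon 1, fell from 10.6 ± 0.042 to 0.613 ± 0.042 CPM, and LRP5, with a 28 nt run, from 14.5 ± 0.93 to 3.43 ± 0.3. MAP3K4 (33 nt), LTBP3 (31 nt), MGST2 (28 nt) and NOTCH4 (32 nt) fell less, with log2 changes of -0.84 to -0.53. The call of NOTCH4 was lost in DESeq2. The MGST2 run lies in a transcript annotated for nonsense-mediated decay. All run lengths are those of the annotation and were not measured in HeyA8 cells. DMPK, with a 62 nt run in the 3' untranslated region, rose by 0.51 ± 0.113, and TCF4, with a 76 nt run in the 5' untranslated region, stood at -0.12 ± 0.059 (adjusted p = 0.066, and adjusted p = 0.049 with only the 4 libraries compared). The 137 genes with CAG runs of at least 19 nt, which a CUG strand can pair with, had a median of -0.19 with siCAG/CUG; 68 were lower and 41 higher (69 and 41 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.19). Matched genes had as low a median in 25 of 10000 draws (permutation p = 0.0052). The genes with the longest CAG runs among the falls included UMAD1 (61 nt, -0.64 ± 0.095), MAML3 (59 nt, -0.79 ± 0.1) and TBP (59 nt). They were picked for having fallen. HTT, also with a 59 nt CAG run, was not called in the main fit, and ATXN1, with a 44 nt run, was higher.

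**Figure D2:**
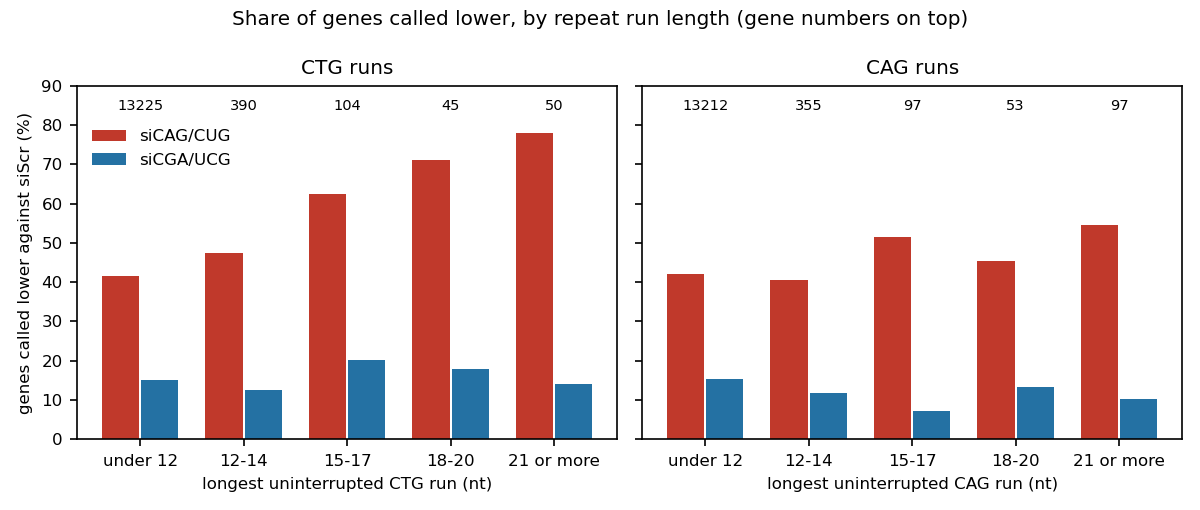
Share of genes called lower against siScr (vertical axis, percent) by the length in nt of the longest uninterrupted CTG run (left) or CAG run (right) in any annotated transcript, for siCAG/CUG (red) and siCGA/UCG (blue), with the number of genes above each pair of bars. For CTG runs the red bars go from 41.6% under 12 nt to 78% at 21 nt or more; the blue bars lie between 12.6% and 20.2%.

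The comparison of siCGA/UCG with siScr asked the same of the CGA and UCG duplex. The largest rises were in CA2, a carbonic anhydrase, from 3.07 ± 0.051 to 11.5 ± 0.037 CPM, and in BIRC3, CPA4, JUNB, CD83, ICAM1, ZDHHC23, N4BP3, IGFN1 and SLC4A11, with log2 changes from 1.75 to 1.17. The largest falls were in HAPLN1, which links hyaluronan and proteoglycan, from 19.3 ± 0.37 to 6.74 ± 0.47 CPM, and in ANK1, PAPPA2, ALPK2, MYO7A, NOV, SCN2A, PLAC1, GPR1 and HTRA1, with log2 changes from -1.45 to -0.87. All 20 had both siCGA/UCG libraries on the same side of both siScr libraries, with an SE of at most 0.18. CA2 (ENSG00000104267) lies on chromosome 8 at 85463902 to 85481492. By limma, 4635 of the 14243 genes passed an adjusted p of 0.05, 2532 higher and 2103 lower with siCGA/UCG (54.6% higher); with a change of at least 1.5-fold as well, 306 passed, 206 higher and 100 lower. The share higher depended on the scaling and on the correction for GC content and length. With DESeq2 size factors in the same fit, 4782 genes passed and 42.9% of them were higher. After the correction, 4666 of 13814 genes passed and 43.9% of them were higher.

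Of 26 genes of NF-kB and inflammation, 20 rose with siCGA/UCG (21 adjusted over the list alone) and none fell, with a median log2 change of 0.51 (adjusted p = 7.8e-17; adjusted p = 0.14 with an estimated correlation). BIRC3 rose from 19.6 ± 0.18 to 65.7 ± 5.3 CPM, ICAM1 from 8.83 ± 0.093 to 21.5 ± 1.2, and the cytokine gene IL1B by 0.59 ± 0.034 and the inhibitor gene NFKBIA by 0.71 ± 0.046. Of 28 ATF4 targets of the integrated stress response, 17 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.25 (adjusted p = 1.1e-06; adjusted p = 0.53 with an estimated correlation); the members that fell include the serine and one-carbon enzymes PHGDH (-0.44 ± 0.062), SHMT2 (-0.28 ± 0.037) and ALDH1L2 (-0.81 ± 0.094), and PPP1R15A rose by 0.39 ± 0.04. Of 23 endoplasmic reticulum chaperones, 13 fell and 1 rose (15 and 2 adjusted over the list alone; median -0.14, adjusted p = 4.3e-05; adjusted p = 0.14 with an estimated correlation), with CALR at -0.29 ± 0.028 and HSP90B1 at -0.27 ± 0.029. Of 20 aminoacyl-tRNA synthetases, 10 fell and none rose (11 fell adjusted over the list alone; median -0.11, adjusted p = 4.3e-05; adjusted p = 0.53 with an estimated correlation). Of 52 G2/M genes, 24 fell and none rose (26 fell adjusted over the list alone), with a median of -0.10 (adjusted p = 1.1e-06; adjusted p = 0.14 with an estimated correlation); BIRC5, a component of the chromosomal passenger complex, fell from 160 ± 3.1 to 126 ± 3.5 CPM.

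Other lists passed as well with siCGA/UCG. Of 79 cytosolic ribosomal proteins, 25 rose and 1 fell, in both adjustments (median 0.05, adjusted p = 0.0002; adjusted p = 0.58 with an estimated correlation). Of 25 cholesterol genes, 11 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.10, adjusted p = 0.00029; adjusted p = 0.53 with an estimated correlation). Of 31 extracellular matrix and mesenchymal genes, 14 fell and 6 rose (14 and 7 adjusted over the list alone; median -0.04, adjusted p = 0.0063; adjusted p = 0.53 with an estimated correlation), with TGFBI at -0.86 ± 0.047 and COL6A1 at 0.81 ± 0.061. Without 1 library each, the median of this list was -0.10 to -0.04. Of 17 abundant structural RNAs, 8 rose and none fell, in both adjustments (median 0.17, adjusted p = 0.0024; adjusted p = 0.24 with an estimated correlation), with the telomerase RNA TERC at 0.84 ± 0.072. The noncoding RNAs of the list include 7SK, and the share of reads on the 7SL and 7SK RNAs was 8.02% and 7.85% in the siCGA/UCG libraries and 7.14% and 6.76% in the siScr libraries. Of 54 S phase genes, 10 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.06), of 31 proteasome subunits 8 fell and none rose, in both adjustments (median -0.03), and of 44 other genes with polyglutamine tracts 15 rose and 2 fell (17 and 2 adjusted over the list alone; median 0.07). These 3 lists each had adjusted p = 0.028, and adjusted p = 0.42, 0.58 and 0.55 with an estimated correlation. Their calls were lost without siScr library 1 (adjusted p = 0.11, 0.19 and 0.061) and without siCGA/UCG library 2 (adjusted p = 0.074, 0.16 and 0.10).

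The remaining lists did not pass with siCGA/UCG. Targets of p53 had 15 of 39 members higher (18 adjusted over the list alone) and 6 lower (adjusted p = 0.077), with CDKN1A at 0.36 ± 0.033; the list passed without siScr library 2 (adjusted p = 0.047) and without siCGA/UCG library 1 (adjusted p = 0.039). Replication-dependent histones had 16 of 57 higher (17 adjusted over the list alone) and 8 lower (adjusted p = 0.41). Epithelial markers had 4 of 9 higher and 1 lower (adjusted p = 0.093; 0.037 without siScr library 2). The others were repeat expansion disease genes (10 genes, 1 higher, 1 lower, adjusted p = 0.81), RNA interference machinery (18 genes, 2 higher, 4 lower, adjusted p = 0.32), core spliceosome (40 genes, 6 higher, 6 lower, adjusted p = 0.96), mitochondrial ribosomal proteins (72 genes, 16 higher, 12 lower, adjusted p = 0.81) and NRF2 genes (25 genes, 5 higher, 9 lower, adjusted p = 0.24). Interferon-stimulated genes (37 genes, 7 higher, 3 lower, 6 and 3 adjusted over the list alone, adjusted p = 0.27) and the CD95 list (8 genes, 1 higher, none lower, adjusted p = 0.81) did not pass either. In 5 lists the sign of the test differed from that of the median or the mean: RNA polymerase II factors (42 genes, 4 higher, 7 lower, 4 and 5 adjusted over the list alone, median 0.05, test down, adjusted p = 0.95), translation factors (35 genes, 9 higher, 3 lower, mean 0.02, median 0.00, adjusted p = 0.81), heat shock genes (14 genes, 2 higher, 1 lower, median 0.00, adjusted p = 0.95), the BCL2 family (28 genes, 6 higher, 6 lower, 8 and 6 adjusted over the list alone, median 0.02 and -0.01 with DESeq2 size factors, test down, adjusted p = 0.81) and endothelial markers (5 genes, 1 higher, 1 lower, median 0.07 and -0.04 after the GC and length correction, test down, adjusted p = 0.95). Without 1 library each, the median ran from -0.08 to 0.13 for endothelial markers, -0.03 to 0.02 for heat shock genes and -0.02 to 0.01 for translation factors.

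A UCG strand can pair with CGA repeats. With siCGA/UCG, IGSF3 and UBL3, the only tested genes with a CGA run of at least 19 nt, both fell. IGSF3 (ENSG00000143061) holds a 21 nt run in the coding sequence of exon 10 of 11, on chromosome 1 at 116579648 to 116579668, and fell from 7.46 ± 0.23 to 3.98 ± 0.063 CPM (adjusted p = 5.7e-06). UBL3 (ENSG00000122042), a ubiquitin-like protein, holds a 19 nt run in the 5' untranslated region of exon 1 of 5, on chromosome 13 at 29849785 to 29849803, and fell from 37.7 ± 1.8 to 20.8 ± 0.2 CPM (adjusted p = 1.2e-10). With siCAG/CUG, UBL3 rose by 0.82 ± 0.049 and IGSF3 fell by 1.51 (SE 0.105). With 2 carriers no list test was made, and no tested gene held a TCG run of at least 19 nt. Genes with CAG runs rose slightly with siCGA/UCG: 40 of 137 rose and 15 fell (44 and 16 adjusted over the list alone), with a median of 0.06 (adjusted p = 0.041; adjusted p = 0.58 with an estimated correlation). That call was lost without siScr library 1 (adjusted p = 0.085), without siCGA/UCG library 2 (adjusted p = 0.11) and against matched genes (permutation p = 0.24).

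**Figure D3:**
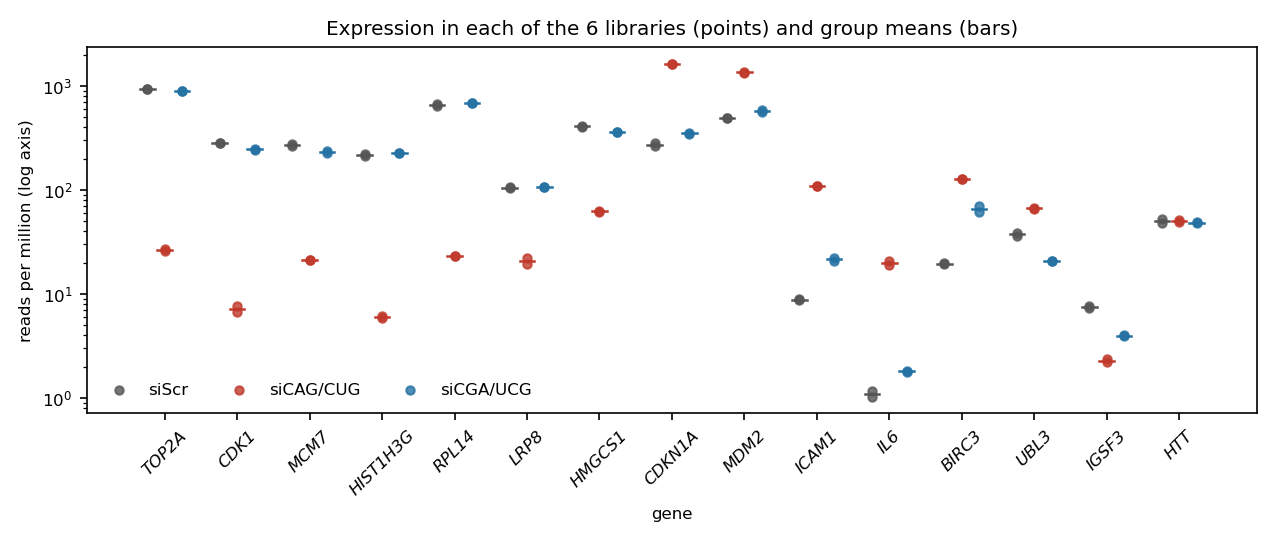
CPM (log axis) of 15 named genes in each of the 6 libraries (points) with group means (bars), for siScr (grey), siCAG/CUG (red) and siCGA/UCG (blue). RPL14 lies at 660, 23.4 and 688 CPM in the 3 groups, and UBL3 at 37.7, 66.7 and 20.8.

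The direct comparison of the siRNAs showed where their changes differed. HJURP, HIST1H3G, CEP55, DLGAP5, TTK and HIST1H1D were lower with siCAG/CUG than with siCGA/UCG, with log2 differences of -5.31 to -5.09. ANGPTL4, SCG5, CCND2, AMIGO2, SULF2 and FAM198B were higher, with differences of 4.74 to 3.42. CDKN1A was higher by 2.21 ± 0.033 and IL6 by 3.14 ± 0.111, and RPL14 differed by -4.85 ± 0.032. In all, 11088 genes differed by limma, 4900 higher and 6188 lower with siCAG/CUG, and 5294 also by at least 1.5-fold (2154 higher, 3140 lower). This balance depended on the scaling as well, with 5480 higher and 5642 lower under TMM factors and 5584 and 5539 under DESeq2 size factors. Of the 27 lists, 15 passed: S phase, G2/M and histones were lower in every tested member, p53 targets were higher in 32 and lower in 5 of 39, and NF-kB genes were higher in 17 and lower in 7 of 26 (adjusted p = 0.012; adjusted p = 0.41 with an estimated correlation). With an estimated correlation only S phase and G2/M of the 15 kept their calls (both adjusted p = 0.021); histones had adjusted p = 0.071 and p53 targets adjusted p = 0.11. Genes with CTG runs were lower in 61 and higher in 10 of 79 (adjusted p = 5.4e-08; adjusted p = 0.039 with an estimated correlation). Genes with CAG runs were lower in 79 and higher in 36 of 137 (81 and 37 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.055), a difference that matched genes reached in 1 of 10000 draws (two-sided permutation p = 0.0004).

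Both siRNAs called 1218 genes higher and 1092 lower, 2310 in the same direction, against 912 and 874 given by the counts alone. The split by direction depended on the processing: 1089 higher and 1340 lower with DESeq2 size factors, 986 and 1226 after the GC and length correction, and 1531 and 852 with library sizes without the 20 most abundant genes. A further 1581 genes were called in opposite directions. Without siScr library 1 the shared calls numbered 1534, and with at least 1.5-fold in both, 106 (71 higher and 35 lower). The 2 comparisons share the siScr libraries, whose chance values they then share, so part of the excess may come from them. The covariance of the log2 changes was 0.0276, against 0.00424 in simulations of unchanged groups with shared controls. The correlation of the log2 changes across genes, which are not independent replicates, was 0.136. In unchanged groups the shared controls alone set this correlation at 0.50, whatever the data. That value does not apply where most genes changed with siCAG/CUG, so it cannot be compared with 0.136. The simulations held at most 1 shared call in the same direction. They contain no changed genes, so they do not measure how much of the excess the shared libraries give.

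**Figure D4:**
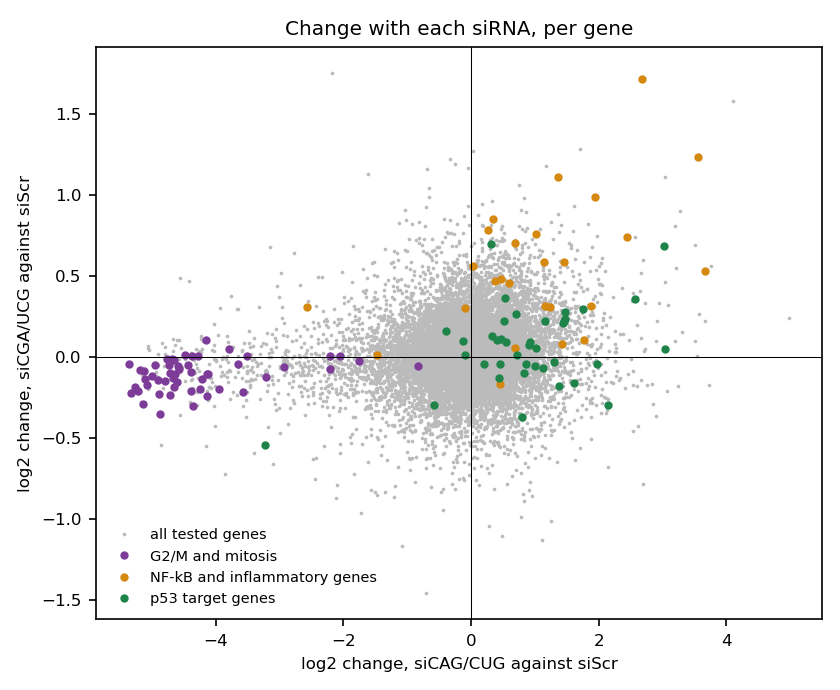
Log2 change of each tested gene (grey) with siCAG/CUG (horizontal axis) and with siCGA/UCG (vertical axis), both against siScr, with G2/M genes (purple), NF-kB and inflammatory genes (orange) and p53 targets (green). The G2/M genes have medians of -4.58 and -0.10 and the NF-kB genes of 1.08 and 0.51; the axes differ in scale.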

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

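TMM factors, the pseudocounts of 0.1 and 1 CPM, edgeR quasi-likelihood and edgeR camera on recovered reads were added to the alternatives later. This was after the files were seen to hold CPM, as was the addition of the lists of genes the authors marked. The plan had named edgeR quasi-likelihood with TMM factors as the gene test for raw counts, and camera on the counts for lists. On recovered reads that gene test gave 5635 genes higher and 5500 lower with siCAG/CUG against siScr. The main fit gave 5128 and 5921. Leaving out a library leaves a group with 1 sample, which is then assumed to vary like the other groups.

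The counts of changed genes stayed within 1.5 times under every scaling, filter, pseudocount and test tried, and without each library, all with no replicate block: 9987 to 11350 for siCAG/CUG against siScr (11049), 3169 to 4854 for siCGA/UCG against siScr (4635; 3169 without siScr library 1) and 10015 to 11201 between the siRNAs (11088). The exception was a change of at least 1.5-fold, which left 5220, 306 and 5294 genes and 106 shared calls, by construction. Shared calls in the same direction (2310) were 1534 to 2062 without 1 library each, the lowest without siScr library 1 (774 higher and 760 lower); the cause was not tested.

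Lists past the threshold numbered 17, 12 and 15 in the 3 comparisons. With a correlation estimated from the data they were 2, 0 and 2. That test also rests on the 3 residual degrees of freedom of the fit. The lost calls can therefore not be put down to correlated members alone. With fry, which tests a list without comparing it with other genes, they were 26, 12 and 26. With siCGA/UCG these were not the same 12: fry did not call ATF4 targets, ribosomal proteins, proteasome, S phase or polyglutamine genes (adjusted p = 0.051 to 0.097), and called RNA interference, translation factors, p53 targets, NRF2 and epithelial markers instead. The direction of fry was the opposite of that of camera for other polyglutamine genes (median -0.0537) and nonsurvival genes (0.0359) with siCAG/CUG against siScr, and for nonsurvival genes between the siRNAs (-0.0285); the cause was not tested. Without 1 library each, 16 to 17, 9 to 14 and 15 to 16 lists passed.

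Genes with CAG runs depended most on the test among the repeat sets. With siCAG/CUG against siScr they passed with fry (-0.19) and against matched genes (-0.19). Between the siRNAs they passed with no filter (-0.23), after the GC and length correction (-0.25), with fry (-0.29), with runs of at least 21 nt (-0.34) and against matched genes (-0.24). With siCGA/UCG they no longer passed with a mean of at least 1 CPM (0.0559), after the GC and length correction (0.0435), with an estimated correlation (0.0622), with edgeR camera (0.0531), with runs of at least 21 nt (0.0499), with protein-coding transcripts only (0.0619) and against matched genes (0.0234). Without 1 library each the median was 0.065 to 0.0789, and the call was lost without siScr library 1 and without siCGA/UCG library 2. The cause was not tested. Genes with CTG runs kept their fall with siCAG/CUG in all 14 other alternatives and without each library.

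HTT with siCAG/CUG passed the threshold only after the GC and length correction, at -0.19, alone or with the replicate block; the cause was not tested. Of the named genes' other alternatives, 2238 of 2268 values kept their direction and their side of the threshold with siCAG/CUG, 2238 of 2288 with siCGA/UCG and 1982 of 2021 between the siRNAs.

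The values showed little sign that the replicate numbers pair the libraries. Deviations of libraries with the same number had correlations of -0.01, 0.06 and 0.03 across 14243 genes, which are not independent replicates. A shared culture or day of libraries with the same number is not excluded by this. With the number as a block, limma called 11141 and 4971 genes against siScr and 11149 between the siRNAs, with the GC and length correction as well 10939, 4919 and 11065, and edgeR quasi-likelihood with the block 11203, 5157 and 11154.

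Depth limits the genes of low level: at the filter of 0.2 CPM a library holds about 10 reads. Replicates differed by more than read sampling, with a chi-square per degree of freedom of 4.17, 3.27 and 4.79 for siScr, siCAG/CUG and siCGA/UCG, so more reads alone would not narrow the spread of abundant genes to sampling noise.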

Other observations

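The tests of gene families, of CGA runs of at least 12 nt and of run length were chosen only after the results were seen. So was the test of the kept calls, and so were the bounds used to judge GC content, length and other repeat classes for CTG runs. The test of GC content and length for the CGA runs was set down before its result. Among 19 families defined by gene name or gene type, several changed with siCAG/CUG against siScr by camera with the preset correlation, none with an estimated one. Only members of the proliferation lists were left out of the families defined by name, so these can share genes with other fixed lists. Of 8 HLA class I genes 7 rose and 1 fell, with a median log2 change of 1.14 (adjusted p = 0.005; adjusted p = 0.24 with an estimated correlation); HLA-B stood at 27.0 CPM in siScr and 97.2 in siCAG/CUG. Of 25 lysosomal genes 16 rose and 7 fell (median 0.50, adjusted p = 0.026; 0.24 with an estimated correlation), of 21 subunits of the vacuolar ATPase 13 rose and 3 fell (median 0.34, adjusted p = 0.0093; 0.24), all 4 metallothionein genes rose (median 1.11, adjusted p = 0.0098; 0.24), and of 34 genes of rRNA processing 24 fell and 3 rose (median -0.29, adjusted p = 0.0083; 0.24).

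With siCGA/UCG, 10 of 17 annexin and S100 genes fell and 1 rose, with a median of -0.17 (adjusted p = 7.9e-06; adjusted p = 0.115 with an estimated correlation). Of 458 genes named ZNF, which code for zinc finger proteins, 244 rose and 101 fell with siCAG/CUG (median 0.23, adjusted p = 0.005; 0.147 with an estimated correlation). With siCGA/UCG 108 rose, 14 fell and 336 passed in neither direction (median 0.10, adjusted p = 0.0032; 0.115 with an estimated correlation). Both values share the siScr libraries, so they are no independent agreement.

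Genes with CTG runs fell with siCAG/CUG. The tables argue against transcript length or GC content as the whole cause, since the median of the carriers was -1.18 after a correction for both. They also argue against any trinucleotide repeat in the transcript, since 1 of the 15 other classes, ATG, had a median under -0.20. Matched genes were as low as the ATG carriers in 1565 of 10000 draws. The CAG carriers missed this bound with a median of -0.19, though matched genes were as low in only 25 of 10000 draws. Pairing of the CAG strand with CUG repeats in the transcript may explain the fall. The change went down with run length across 589 genes with runs of at least 12 nt (Spearman rho = -0.338). The permutation p was 1e-05, the smallest these permutations can give. Without runs of at least 21 nt, rho was -0.294 (n = 539). The permutations of run length, here and below, treat genes as independent, which they are not. They used changes without the GC and length correction. With siCGA/UCG the same relation was -0.0286 (permutation p = 0.49). With siCAG/CUG, carriers of runs of at least 19 nt had a median of -1.46 where the run lies in the coding sequence (50 genes). The median was -0.69 for runs in the 5' untranslated region (12 genes) and -0.66 in the 3' untranslated region (9 genes). Other traits that the carriers may share were not tested, and the pairing itself was not measured.

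Many genes changed a little between siCGA/UCG and siScr. The changes went up with GC content across genes (Spearman rho = 0.286). After the GC and length correction, 2049 genes were called higher and 2617 lower, against 2532 and 2103 in the main fit. A trend with GC content or length is still not the whole cause, since 82.3% of the calls were kept in the same direction after the correction (3770 of 4582). Scaling by a few abundant genes is not the whole cause either, with 93.5% kept (4333 of 4635). Nor did the calls rest on 1 siScr library: 65.6% were kept without siScr library 1 (3039 of 4631) and 76.8% without library 2. An effect of the siRNA and a difference between cultures stay open, since each group holds 2 libraries and the labels do not say which were grown together.

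Of 35 tested genes with a CGA run of at least 12 nt, 14 were lower and 4 higher with siCGA/UCG, with a median of -0.07 that 19 of 10000 matched draws reached; with siCAG/CUG 19 were lower and 12 higher (median -0.16, 1249 of 10000 draws), and between the siRNAs 14 were lower and 12 higher (median 0.01), so a fall of CGA carriers particular to siCGA/UCG was not shown. The 11 genes with TCG runs of at least 12 nt, which the CGA strand can pair with, had 4 lower and 1 higher with siCGA/UCG (median -0.07), 8 higher and 3 lower with siCAG/CUG against siScr (median 0.22), and 8 higher and 2 lower with siCAG/CUG than with siCGA/UCG (median 0.62); camera over n = 11 genes gave p = 0.0046, p = 0.059 and p = 0.0091 with the preset correlation, and p = 0.118, p = 0.243 and p = 0.138 with an estimated one. Transcript length or GC content does not account for the lower values, as the median was -0.20 after the correction and camera over the 35 genes (n = 35) gave p = 1.1e-06, though before the correction the set did not pass with an estimated correlation (p = 0.144). Pairing of the UCG strand with CGA repeats in the transcript cannot be told apart from an effect of 3 genes: the change went down with run length (rho = -0.347, permutation p = 0.0421, n = 35), but without IGSF3, UBL3 and CEP170, whose runs are at least 18 nt, rho was -0.16 (permutation p = 0.379, n = 32).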
